A study of Rattus norvegicus with 8 samples.

How the data were processed

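RNA was measured in vascular smooth muscle cells isolated from the thoracic aorta of male Sprague-Dawley rats, with Affymetrix arrays that carry many short-probe sets, each summarised to 1 value. Per the labels' protocols, cells grew in medium with 10% serum for 2 passages and received siRNA for 48 h, either a non-targeting control (siNTC) or an siRNA against Giver (siGiver). They then received 100 nM angiotensin II (Ang II) or phosphate-buffered saline (PBS) for 3 h. Per the labels, 5 ug of total RNA per array was labelled with biotin by the one-cycle protocol.

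The deposited values are on a log2 scale, 1 per probe set and array, and range from 2.06 to 14.6. The submitters' processing notes name RMA and Partek, and the versions are not given in the sources used here. RMA is a method that corrects background, applies quantile normalization between arrays and fits 1 value per probe set, so levels are comparable between arrays for 1 probe set and not between probe sets. Array medians of the deposited log2 values lay between 6.15 and 6.19. Arrays have no read depth, and the number of arrays limits the precision.

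Samples were grouped by the labels into 4 groups of 2 arrays. The labels do not say whether the arrays of a group came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. The 2 arrays of a group correlated at 0.998 in every group, with a standard deviation (SD) of their difference between 0.113 and 0.119 log2, and shared at most 66 identical values among 31099 probe sets. No scan date or slide was used here, so batches between the arrays were not tested.

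Probe sets were named through GEO's annotation of the array. Of the 31099 probe sets, 57 are controls, 20832 carry 1 gene symbol, 436 carry several and 9780 are not listed there. Symbols were looked up by gene identifier in a table of rat genes, where 20764 of the 20832 matched. Probe sets with several symbols or none were not named. After leaving out probe sets with a mean below the 30th percentile (4.81 log2), the brightest probe set of each symbol was kept, which gave 11377 genes. No probe set is annotated as Giver, so the knockdown itself was not analysed here. Some genes planned for reporting are not reported here.

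A linear model with 1 mean per group was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3 (4 residual degrees of freedom, 3.53 prior degrees of freedom), and 7 contrasts were tested with moderated statistics. These were Ang II in each siRNA arm, the siRNA in each treatment, both averages, and the interaction, which is the Ang II effect in siGiver cells minus that in siNTC cells. Benjamini-Hochberg adjusted p under 0.05 counted as changed, and errors are standard errors (SE) of the fit unless said otherwise. For 3 contrasts, 20 of 21 gene lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. The endothelial list had only 2 measured members and was not tested. Of 333 list members, 270 were tested and 28 lay below the filter. Genes raised or lowered by Ang II averaged over both siRNAs (adjusted p under 0.05, at least 1.5-fold) were tested as sets on the interaction with fry, since these contrasts are orthogonal in a balanced design.

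Named genes were chosen by a rule written before the data were examined, like the contrasts, lists and alternatives. It takes, per contrast and direction, the 10 genes with the largest change among those past the threshold whose arrays do not overlap between the groups compared (for the interaction, past the threshold only). If fewer than 5 passed in a direction, the 5 with the smallest p were to be given as not passing, which did not arise. Uninformative clone and locus names were skipped. Nr4a3, Nox1, Il6, Ccl2, Tnf, Fos, Egr1, Agtr1a and Acta2 are always given, and up to 4 members with the smallest p are named per list. The text leaves out some of these names.

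The scripts were tested on simulated data for 11377 genes, with 50 genes changed by each of 4 known folds. Means were the measured ones, each gene's spread was drawn from the model's fitted prior, and noise was independent between genes. For the Ang II effect in siNTC cells, 58% of genes changed 1.25-fold, 84% of those changed 1.5-fold and 100% of those changed by 2 or 3 were recovered, with 9 false among 180 calls. For the interaction, 4% of genes changed 1.25-fold and 68% of those changed 1.5-fold were recovered, with 7 false among 138 calls. With an equal Ang II effect simulated in both arms, the chosen set's median interaction stayed within 0.0222 log2 of 0 in 50 runs. Its fry p was under 0.05 in 3 of these runs, and any list passed in 3. The simulated genes were not correlated, so these runs do not show how the list and set tests behave with correlated genes.

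Alternatives were no filter, a filter at the 50th percentile, the mean of a gene's probe sets, every probe set on its own, cyclic loess, subtraction of array medians, trended and robust moderation, array weights, the replicate number as a block, each array left out in turn, other thresholds, and only the 4 arrays compared. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.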

Results

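The data comprise 8 arrays of rat aortic smooth muscle cells, 2 for each combination of siRNA (siNTC or siGiver) and treatment (PBS or Ang II). Giver is a long non-coding RNA of vascular smooth muscle cells, and Ang II is a peptide hormone that constricts vessels and drives growth and inflammatory gene expression in these cells. The design asks how cells given Giver siRNA differ from control cells, and how each responds to Ang II. Over the 11377 genes tested, the first principal component held 59.6% of the variance and separated the siRNA arms. The second component held 22.7% and separated Ang II from PBS in both arms.

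In siNTC cells, 3 h of Ang II raised transcripts of immediate early and interferon response genes. Nfil3, a leucine zipper transcription factor, rose by 1.81 ± 0.065 on the log2 scale (SE, 2 arrays per group), or 3.52-fold. Mx1, an interferon-induced antiviral GTPase, rose by 1.77 ± 0.050 (3.41-fold), and Rgs16, a regulator of G-protein signalling, by 1.67 ± 0.12 (3.18-fold). The chemokines Cxcl11 and Cxcl9 rose by 1.62 ± 0.071 and 1.31 ± 0.071. Among signalling genes, the calcineurin inhibitor Rcan1 rose by 1.61 ± 0.063, and the orphan nuclear receptor Nr4a3 by 1.51 ± 0.096. The nucleic acid sensor Zbp1, Tcim and Ifit3 rose by 1.38, 1.32 and 1.32. Falls were smaller, led by the transporter gene Abca8a at -0.82 ± 0.10 or below (its level with Ang II, 4.44, was under the filter value), Col6a3 at -0.70 ± 0.12, the Ang II receptor gene Agtr1a at -0.67 ± 0.046 and Pla2r1 at -0.59 ± 0.043. The Col6a3 call was lost when either siNTC PBS array or siNTC Ang II replicate 1 was left out.

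Interferon response genes formed the list with the highest median, 0.78 log2, and 17 of 18 measured members rose (18 adjusted over the list alone), among them Ccl5 by 1.19 and Cxcl10 by 0.90. Its camera adjusted p was 1.88e-29, and adjusted p = 0.0234 with an estimated correlation. The control probe set for 5S ribosomal RNA stood highest in the same group, at 8.90 ± 0.032 (SD, n = 2) in siNTC Ang II arrays against 8.20 ± 0.066 in siNTC PBS arrays. Of 24 immediate early transcription factors, 15 rose (17 adjusted over the list alone), including Egr1 by 0.72, Fosl1 by 0.64 and Egr2 by 0.82, with adjusted p = 1.08e-14, and adjusted p = 0.0234 with an estimated correlation. Of 17 inflammatory cytokines, chemokines and adhesion molecules, 9 rose (11 and 1 lower adjusted over the list alone), including Il6 by 0.63, Ccl7 by 0.50, Ccl20 by 0.55 and Cxcl2 by 0.79 (adjusted p = 1.38e-06, and adjusted p = 0.0347 with an estimated correlation). Ccl2 rose by 0.28 ± 0.045, a call lost when any array of the siNTC groups was left out. Tnf stood at -0.08 ± 0.079 and did not pass, while its dimmer probe set rose by 0.56 (adjusted p = 0.0016 among all probe sets).

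Other lists passed at the preset correlation and not with an estimated one. Of 14 MAPK and G-protein feedback regulators, 8 rose (10 and 1 lower adjusted over the list alone), including Rgs2 by 0.94 and Spry2 by 0.64 (adjusted p = 4.65e-09, and adjusted p = 0.0638 with an estimated correlation). Of 17 growth factors and ligands, 7 rose and 1 fell (10 and 2 adjusted over the list alone), with Ereg at 0.64, Bdnf at 0.46, Hbegf at 0.49 and Areg at 0.81 (adjusted p = 0.000459, and adjusted p = 0.0638 with an estimated correlation). The stress response list had 4 of 14 members higher (8 and 1 lower adjusted over the list alone), namely Ddit3 at 0.55, Chac1 at 0.35, Trib3 at 0.23 and Atf4 at 0.20 (adjusted p = 0.000273, and adjusted p = 0.0807 with an estimated correlation). Of 11 NF-kB feedback and target genes, Irf1 (0.40) and Nfkbia (0.23) rose (8 adjusted over the list alone), with adjusted p = 0.000162, and adjusted p = 0.0816 with an estimated correlation. Sod2 (0.39), Mt2A (0.28) and Srxn1 (0.22) rose among 16 antioxidant genes (5 and 1 lower adjusted over the list alone; adjusted p = 0.0165, and adjusted p = 0.243 with an estimated correlation). Aen (0.23) rose among 12 p53 target genes (6 and 1 lower adjusted over the list alone; adjusted p = 0.0237, and adjusted p = 0.198 with an estimated correlation).

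Lists that passed downward were contractile genes, matrix genes and fibroblast markers. Of 17 smooth muscle contractile genes, Myh11 (-0.29), Cald1 (-0.22) and Acta2 (-0.19 ± 0.044) fell (8 adjusted over the list alone), with adjusted p = 0.000975, and adjusted p = 0.0661 with an estimated correlation. The Acta2 call was lost without the filter, with array medians subtracted, and when any 1 array was left out. Of 21 matrix and remodelling genes, 5 fell and 1 rose (10 and 2 adjusted over the list alone), with Fbn1 at -0.28, Lox at -0.22, Col5a1 at -0.22 and the matricellular gene Ccn1 at 0.41 (adjusted p = 0.000459, and adjusted p = 0.0816 with an estimated correlation). Of 8 fibroblast markers, Dcn (-0.42), Pdgfra (-0.38), Scara5 (-0.39) and Lum (-0.25) fell (4 adjusted over the list alone), with adjusted p = 0.000347, and adjusted p = 0.0816 with an estimated correlation. Nox1, the catalytic subunit of an NADPH oxidase, rose by 0.44 ± 0.056, the only one of 6 measured subunits to pass (1 adjusted over the list alone; list adjusted p = 0.413). The lists that did not pass were cell cycle genes (adjusted p = 0.468), renin-angiotensin genes (0.807; median 0.07, mean -0.08), cholesterol genes (0.441), heat shock genes (0.0778), hypoxia and glycolysis genes (0.156), macrophage markers (0.362) and reference genes (0.317).

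In all, limma called 698 genes in siNTC cells, 451 higher and 247 lower, of which 91 and 5 changed at least 1.5-fold. The count was 226 without siNTC PBS replicate 1, 357 without siNTC PBS replicate 2, 274 without siNTC Ang II replicate 1 and 228 without siNTC Ang II replicate 2, and ranged up to 1496 with trended, robust moderation.

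In siGiver cells, Rgs16 rose with Ang II by 3.17 ± 0.12 (9.003-fold), Fam110c by at least 3.05 ± 0.10, its siGiver PBS level (4.59) being below the filter value of 4.81, the serpin gene Serpinb2 by 2.83 ± 0.096 (7.09-fold) and Nr4a3 by 2.71 ± 0.096 (6.57-fold). Nfil3, Nr4a1 and Rcan1 rose by 2.58, 2.51 and 2.47. Egr2, the prostaglandin synthase gene Ptgs2 and the ERK phosphatase gene Dusp5 rose by 2.30, 2.18 and 2.14. Lower were Ackr3, a scavenging chemokine receptor, by -1.21 ± 0.053, Pik3ip1 by -1.03 ± 0.055, Lurap1l by -0.89, Sash1 by -0.81, Rnf122 by -0.81 and Klf15 by -0.79 ± 0.056.

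Counted by gene, 18 of 24 immediate early factors and 12 of 14 MAPK and G-protein feedback regulators rose (19 and 12 rose adjusted over the list alone). Among inflammatory genes 9 of 17 rose (9 adjusted over the list alone), and Il6 (0.69 ± 0.045) and Ccl2 (0.35 ± 0.045) were among them. Of the 18 interferon response genes, Ifih1 (0.41), Oasl (0.33) and Cxcl10 (0.26) rose, Mx1 (-0.19) and Irf7 (-0.17) fell and 13 did not pass (3 higher and 2 lower adjusted over the list alone). Fos rose by 1.27 ± 0.076, Egr1 by 1.68 ± 0.047 and Nox1 by 0.44 ± 0.056, Agtr1a fell by 0.53 ± 0.046 on the log2 scale, and Acta2 (0.04) and Tnf (-0.10) did not pass. Limma called 1852 genes, 1036 higher and 816 lower, and 192 and 36 of these changed at least 1.5-fold. With array medians subtracted, the split was 1164 higher and 561 lower. The count fell to 881 without siGiver PBS replicate 1, 1156 without siGiver PBS replicate 2, 1037 without siGiver Ang II replicate 1 and 866 without siGiver Ang II replicate 2.

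The genes that rose with Ang II in both arms numbered 197, against 41.1 for independent lists, and 68 fell in both, against 17.7. Both contrasts take each gene's spread from the same fit, so the lists are not independent even without a shared effect. Genes higher in siNTC and lower in siGiver cells numbered 28, against 32.35, and the reverse 6, against 22.5. Across genes, which are not independent replicates, the 2 Ang II effects correlated at r = 0.42.

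**Figure D1:**
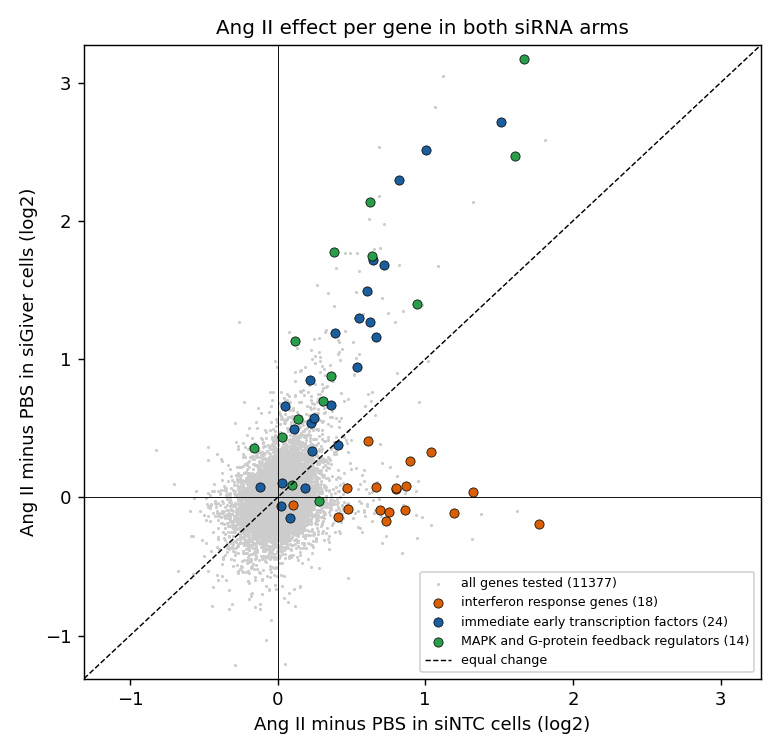
Each point is 1 gene, with the Ang II effect in siNTC cells (log2, x axis) against that in siGiver cells (log2, y axis), and members of 3 lists coloured. Interferon response genes lie near 0 on the y axis (list median -0.01, which was 0.02 with array medians subtracted), while immediate early factors have a median of 0.375 in siNTC cells and 0.76 in siGiver cells.

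Without Ang II, Emc10 had the largest positive difference between siGiver and siNTC cells among the named genes. Transcripts higher in siGiver than siNTC cells in PBS included Emc10, a subunit of the endoplasmic reticulum membrane complex, by 2.37 ± 0.058 (5.18-fold), Mfge8, a secreted glycoprotein of the arterial wall, by 1.88 ± 0.056 (3.68-fold), and the clathrin light chain gene Clta by 1.76 ± 0.060. C2h4orf3, Adam19 and Tpp1 were higher by 1.40, 1.39 and 1.35. The matrix proteoglycan gene Aspn was lower, at -2.03 ± 0.067 or below, taken as a bound because its siGiver level (4.16) lay below the filter value of 4.81. The transcription factor genes Foxq1 and Dach1 were lower by -1.81 ± 0.065 and -1.76 ± 0.12. Ptgs2 was lower by -1.67 ± 0.088, the oxygen sensor gene Egln3 by -1.58 ± 0.060, Nox1 by -1.51 ± 0.056 and Tnfaip6 by -1.39 ± 0.060.

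Lists were not tested in this comparison. Counted by gene in PBS, 22 of 24 cell cycle genes and 12 of 17 contractile genes were higher (22 and 13 adjusted over the list alone), with Mcm7 at 0.90, Cdk1 at 0.70, Myh11 at 0.59 and Cnn1 at 0.54. Of 21 matrix genes, 9 were lower and 1 higher (12 and 2 adjusted over the list alone). Of 24 immediate early factors, 8 were higher and 8 lower (8 and 9 adjusted over the list alone; median -0.039, mean 0.0011), and of 14 MAPK and G-protein feedback regulators, 4 were higher and 4 lower (5 and 4 adjusted over the list alone; median 0.095). Of 17 inflammatory genes, 9 were lower and 2 higher (9 and 2 adjusted over the list alone), among them Il6 at -0.54 ± 0.045, Cx3cl1 at -0.51 and Ccl2 at -0.36 ± 0.045. Interferon response genes had 3 higher and 1 lower of 18 (3 and 1 adjusted over the list alone), with Gbp2 at 0.77, Cxcl10 at 0.55, Ccl5 at 0.39 and Usp18 at -0.35. Fos was higher by 0.35 ± 0.076, Agtr1a by 0.24 ± 0.046 and Acta2 by 0.14 ± 0.044, Nr4a3 lower by -0.34 ± 0.096, and Egr1 (0.01) and Tnf (-0.04) did not pass. The Acta2 call was lost without the filter and when any 1 array was left out, and the Fos call without siNTC PBS replicate 1. The Nr4a3 call was lost with the mean of its probe sets and without either siNTC PBS array or siGiver PBS replicate 1. Limma called 3986 genes, 1817 higher and 2169 lower, of which 290 and 205 changed at least 1.5-fold. With cyclic loess the split turned to 2054 higher and 1980 lower.

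With Ang II present, the siRNA arms differed by more genes. Emc10, Adam19, Mfge8 and Clta were again higher in siGiver cells, by 2.28 ± 0.058, 1.94 ± 0.058, 1.93 ± 0.056 and 1.83 ± 0.060. Dusp5 was higher by 2.24 ± 0.067 (4.73-fold), the scaffold gene Akap12 by 1.76 ± 0.051, the hexokinase gene Hk2 by 1.70 ± 0.12, the interleukin 33 receptor gene Il1rl1 by 1.67 ± 0.044, Fosl1 by 1.4998 ± 0.044 and Dusp6 by 1.48 ± 0.050. Aspn was lower, at -2.38 ± 0.067 or below, and Cxcl9 at -2.28 ± 0.071 or below, with siGiver levels of 3.83 and 4.71, below the filter value. Other interferon-inducible genes were lower, Mx1 by -2.01 ± 0.050, Gbp4 by -1.90 ± 0.071, Cxcl11 by -1.90 ± 0.071 and Zbp1 by -1.82 ± 0.087. Nox1 was lower by -1.51 ± 0.056, Il6 by -0.48 ± 0.045 and Ccl2 by -0.29 ± 0.045.

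By gene, 16 of 18 interferon response genes were lower (16 adjusted over the list alone). Of 24 immediate early factors, 18 were higher and 2 lower (19 and 2 adjusted over the list alone; median 0.52). Of 14 MAPK and G-protein feedback regulators, 12 were higher (13 adjusted over the list alone; median 0.68). Of 21 matrix genes, 8 were higher and 4 lower (8 and 4 adjusted over the list alone; median 0.023). Of 24 cell cycle genes, 20 were higher and 1 lower (20 and 1 adjusted over the list alone). Nr4a3 was higher by 0.86 ± 0.096, Fos by 0.99 ± 0.076, Egr1 by 0.97 ± 0.047, Agtr1a by 0.38 ± 0.046 and Acta2 by 0.37 ± 0.044. Tnf (-0.06) did not pass, but did with the mean of its probe sets (-0.257, adjusted p = 0.00473). Limma called 5037 genes, 2219 higher and 2818 lower, of which 411 and 344 changed at least 1.5-fold. Of these calls, 1352 higher and 1570 lower genes were also called in that direction in PBS, against 354.4 and 537.2 for independent lists. These lists also share each gene's spread from the same fit. Genes higher in PBS and lower with Ang II numbered 24, against 450.1, and the reverse 49, against 423.

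**Figure D2:**
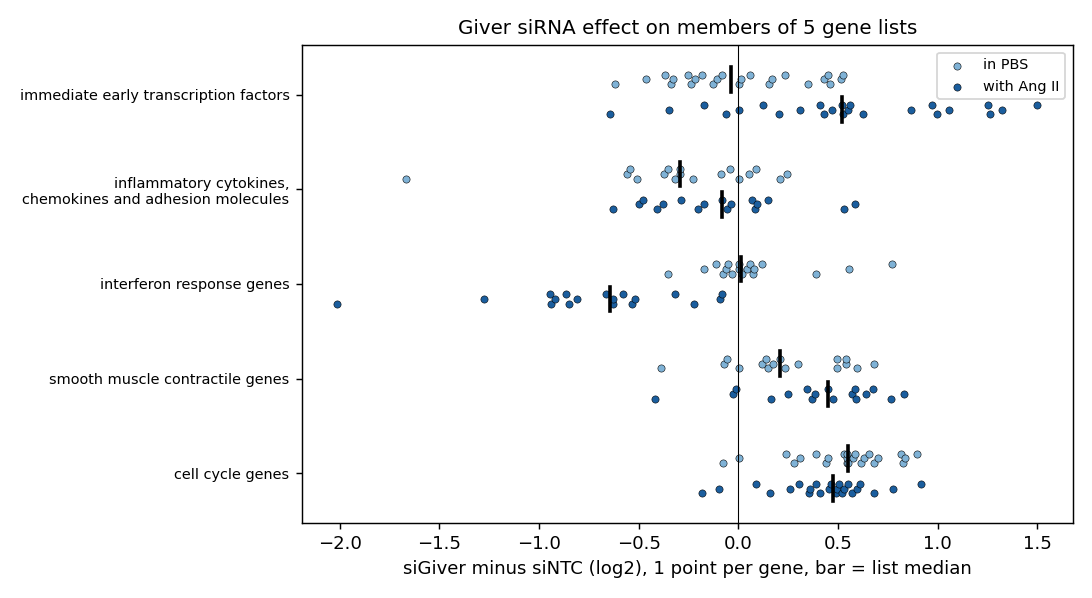
Points are genes of 5 lists, placed by siGiver minus siNTC (log2, x axis) in PBS or with Ang II, and bars are list medians. The cell cycle median is 0.55 in PBS and 0.48 with Ang II, and the interferon median is 0.01 in PBS and -0.65 with Ang II.

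Averaged over PBS and Ang II (4 arrays against 4), Emc10 was higher in siGiver cells by 2.33 ± 0.041 (5.02-fold), Mfge8 by 1.91 ± 0.040, Clta by 1.80 ± 0.043, Adam19 by 1.66 ± 0.041 and Dusp5 by 1.49 ± 0.047. Naa60, Dcaf7, Sh3bgr and Il1rl1 followed at 1.38, 1.37, 1.32 and 1.31. Aspn was lower, at -2.21 ± 0.048 or below, with siGiver levels below the filter value. Foxq1 was lower by -1.56 ± 0.046, Nox1 by -1.51 ± 0.040 (2.85-fold), Cxcl9 by -1.47 ± 0.050 or below (dim in siGiver cells with Ang II) and Egln3 by -1.44 ± 0.043. Il6 was lower by -0.51 ± 0.032 and Ccl2 by -0.32 ± 0.032, Fos was higher by 0.67 ± 0.054, Egr1 by 0.49 ± 0.034, Agtr1a by 0.31 ± 0.032, Nr4a3 by 0.26 ± 0.068 and Acta2 by 0.25 ± 0.031, and Tnf (-0.05) did not pass, but did with the mean of its probe sets (-0.206, adjusted p = 0.00203). The Nr4a3 call was lost without siNTC PBS replicate 2, and its average joins a lower level in PBS (-0.34) with a higher one with Ang II (0.86).

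Cell cycle genes had the highest list median, 0.53 log2, with 22 of 24 higher (22 and 2 lower adjusted over the list alone), including Mcm7 at 0.79, Cdk1 at 0.61, Mki67 at 0.80 and Bub1 at 0.56. Its camera adjusted p was 1.42e-10, and adjusted p = 0.0688 with an estimated correlation. Of 17 contractile genes, 13 were higher and 1 lower (13 and 1 adjusted over the list alone), including Myh11 at 0.71, Cnn1 at 0.65, Synpo2 at 0.62 and Lmod1 at 0.54 (adjusted p = 2e-05, and adjusted p = 0.0688 with an estimated correlation). Of 14 MAPK and G-protein feedback regulators 10 were higher (10 adjusted over the list alone), including Dusp6 at 0.79, Dusp14 at 0.65 and Errfi1 at 0.61 (adjusted p = 0.000108, and adjusted p = 0.182 with an estimated correlation). Among immediate early factors 16 were higher and 4 lower (16 and 4 adjusted over the list alone), with Fosl1 at 0.96, Myc at 0.75, Fosb at 0.92 and Klf2 at -0.63 (adjusted p = 0.000324, and adjusted p = 0.18 with an estimated correlation). The MAPK and immediate early medians were 0.095 and -0.039 in PBS against 0.68 and 0.52 with Ang II. Interferon response genes were lower in 16 of 18 and higher in 2 (16 and 2 adjusted over the list alone), with Mx1 at -1.03, Usp18 at -0.65, Ifit3 at -0.64 and Rsad2 at -0.47 (adjusted p = 6.07e-05, and adjusted p = 0.18 with an estimated correlation). The interferon median was 0.011 in PBS against -0.646 with Ang II. The 5S ribosomal RNA control was lower in siGiver arrays too, at 7.63 ± 0.011 in PBS and 7.74 ± 0.037 with Ang II (SD, n = 2).

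The inflammatory list had 10 of 17 members lower and 2 higher (10 and 2 adjusted over the list alone), with Cx3cl1 at -0.57, Ptgs2 at -0.92 and Icam1 at 0.39, and did not pass as a list (adjusted p = 0.123). NADPH oxidase subunits did not pass either (adjusted p = 0.285), with Nox1, Rac1 (-0.25), Cyba (-0.23) and 1 more lower and Nox4 (0.42) higher (4 and 1 adjusted over the list alone). Other lists that did not pass were NF-kB targets (2 higher and 4 lower; adjusted p = 0.995; median 0.01, mean -0.0054), matrix genes (6 and 11; 0.689) and growth factors (8 and 5; 0.181). Renin-angiotensin genes (1 and 1; 0.953), stress response genes (6 and 2; 0.172) and heat shock genes (3 and 3; 0.794; median 0.0047, mean -0.0020) did not pass. Nor did macrophage markers (2 lower; 0.536), fibroblast markers (3 higher and 1 lower; 0.217) or reference genes (2 lower; 0.698). Limma called 5938 genes, 2624 higher and 3314 lower, or 52.2% of those tested, and 297 and 217 of them changed at least 1.5-fold.

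The interaction asks whether the Ang II effect differs between the siRNA arms. The Ang II effect was higher in siGiver cells by at least 1.93 ± 0.14 log2 for Fam110c (dim in siGiver PBS), 1.76 ± 0.14 for Serpinb2, 1.53 ± 0.072 for Akap12, 1.52 ± 0.094 for Dusp5, 1.503 ± 0.15 for Nr4a1 and 1.496 ± 0.12 for Ptgs2. Akap12 fell by 0.26 on the log2 scale in siNTC cells and rose by 1.27 in siGiver cells, and the other 5 rose in both arms. Ptgs2 started 1.67 log2 lower in PBS and reached 12.2 in siGiver against 12.3 in siNTC cells with Ang II. The Ang II effect on interferon-induced genes was lower in siGiver cells, by -1.96 ± 0.071 for Mx1, -1.72 ± 0.10 for Cxcl11, -1.61 ± 0.10 or below for Cxcl9 (dim in siGiver cells with Ang II), -1.497 ± 0.12 for Zbp1, -1.31 ± 0.074 for Ccl5 and -1.28 ± 0.076 for Ifit3. Nr4a3 differed by 1.202 ± 0.14, Egr1 by 0.96 ± 0.067 and Fos by 0.64 ± 0.11, in log2. The Fos call was lost with the mean of its probe sets (0.17, adjusted p = 0.337) and without siNTC PBS replicate 2, siNTC Ang II replicate 2 or siGiver Ang II replicate 1.

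Nox1, Il6 and Ccl2 were lower in siGiver cells with and without Ang II, and their interactions did not pass. The interaction was 0.0042 for Nox1 (95% interval -0.18 to 0.19), 0.07 for Il6 (-0.08 to 0.22) and 0.07 for Ccl2 (-0.08 to 0.22). It did not pass for Agtr1a (0.14, interval -0.01 to 0.29), Acta2 (0.23, interval 0.09 to 0.38, adjusted p = 0.0688) or Tnf (-0.02). With trended, robust moderation the Acta2 interaction passed (adjusted p = 0.000995).

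**Figure D3:**
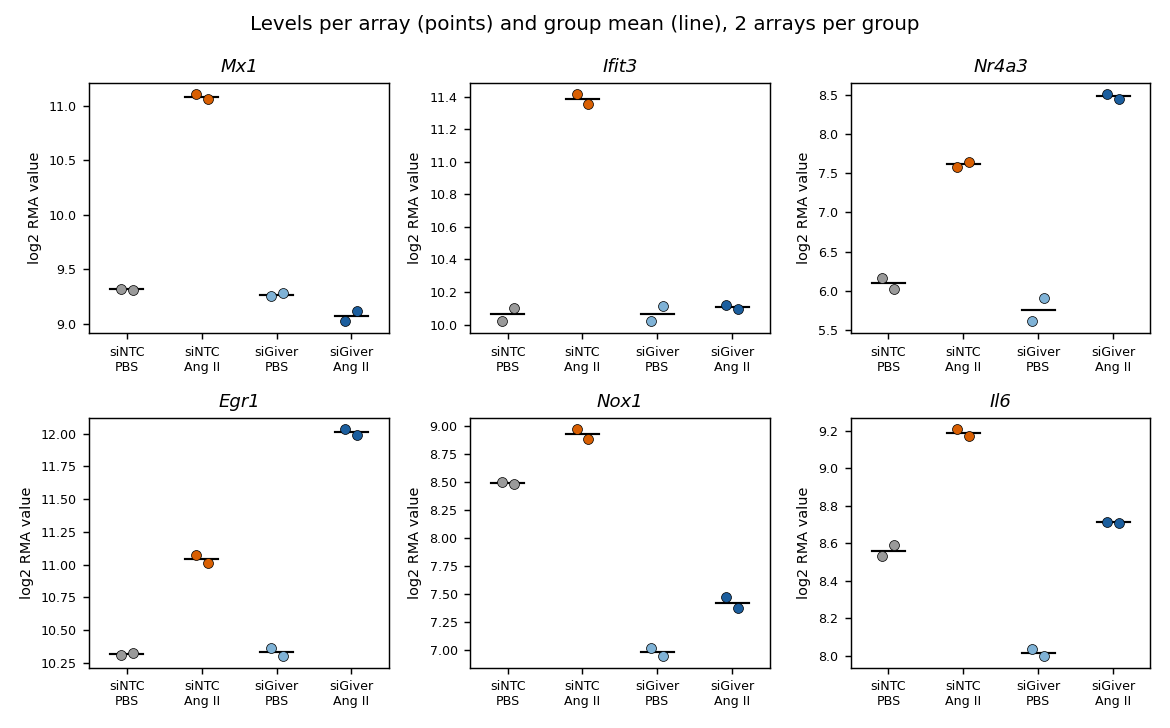
Each panel gives 1 gene's log2 value on every array (points, y axis) by group (x axis), with the group mean as a line and 2 arrays per group; y axes do not start at 0. Mx1 averages 11.1 in siNTC Ang II cells and 9.07 in siGiver Ang II cells, while Nox1 averages 8.93 and 7.42 there.

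Of 24 immediate early factors, 16 had a higher Ang II effect in siGiver cells (17 adjusted over the list alone), including Egr2 at 1.48, Fosl1 at 1.07 and Ier2 at 0.75 (adjusted p = 5.01e-15, and adjusted p = 0.0224 with an estimated correlation). Of 18 interferon response genes, 15 had a lower effect there (18 adjusted over the list alone), including Irf7 at -0.90, with a list median of -0.74 (adjusted p = 1.11e-22, and adjusted p = 0.0224 with an estimated correlation). Of 14 MAPK and G-protein feedback regulators, 11 had a higher effect (12 and 1 lower adjusted over the list alone), including Dusp6 at 1.39, Errfi1 at 1.01 and Spry2 at 1.10 (adjusted p = 1.24e-12, and adjusted p = 0.0505 with an estimated correlation). Matrix genes had 4 of 21 higher (11 adjusted over the list alone), Tnc at 0.95, Ccn1 at 0.73, Col5a1 at 0.40 and Eln at 0.38 (adjusted p = 1.52e-07, and adjusted p = 0.0505 with an estimated correlation). Col5a1 fell with Ang II in siNTC cells (-0.22) and rose in siGiver cells (0.18). Growth factors had 5 of 17 higher and 1 lower (7 and 2 adjusted over the list alone), with Hbegf at 1.28, Edn1 at 0.62, Pdgfa at 0.48 and Gdf15 at -0.68 (adjusted p = 0.000514, and adjusted p = 0.0505 with an estimated correlation). Contractile genes had Vcl (0.41) and Tpm1 (0.30) higher of 17 (7 adjusted over the list alone), with adjusted p = 0.000278, and adjusted p = 0.0505 with an estimated correlation.

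The inflammatory list had 4 of 17 higher (5 adjusted over the list alone), including Ptgs2, Cxcl1 (0.34), Ccl20 (0.38) and Icam1 (0.29), with adjusted p = 0.0238, and adjusted p = 0.143 with an estimated correlation. Sesn1 (-0.53), Sesn2 (-0.35) and Cdkn1a (-0.35) had a lower effect among 12 p53 target genes (6 adjusted over the list alone; adjusted p = 0.00459, and adjusted p = 0.143 with an estimated correlation). Limma called 0 of 24 cell cycle genes, also adjusted over the list alone, and 6 had unadjusted p under 0.05. Their list passed downward with a median of -0.10 (adjusted p = 0.0203, and adjusted p = 0.262 with an estimated correlation). Lists that did not pass were NF-kB targets (adjusted p = 0.306), NADPH oxidase subunits (0.614), antioxidant genes (0.41), renin-angiotensin genes (0.306) and cholesterol genes (0.41). Nor did heat shock genes (0.0592), hypoxia genes (0.306), macrophage markers (0.242), fibroblast markers (0.252) or reference genes (0.595). Stress response genes did not pass (0.881; median -0.0072, mean -0.019, tested direction up). Limma called 707 genes in the interaction, 381 higher and 326 lower. The count lay between 356 (without siNTC Ang II replicate 1) and 435 (without siGiver PBS replicate 2) when any 1 of the 8 arrays was left out, and was 1490 with trended, robust moderation.

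Averaged over both siRNAs, Ang II raised Rgs16 by 2.42 ± 0.083, Nfil3 by 2.20 ± 0.046, Nr4a3 by 2.11 ± 0.068, Fam110c by at least 2.08 ± 0.071 and Rcan1 by 2.04 ± 0.044, and lowered Ackr3 by -0.75 ± 0.037, Tbx18 by -0.62 ± 0.046 and Agtr1a by -0.60 ± 0.032. Egr1 rose by 1.204 ± 0.034, Fos by 0.95 ± 0.054, Il6 by 0.66 ± 0.032, Nox1 by 0.44 ± 0.040 and Ccl2 by 0.32 ± 0.032, and Acta2 (-0.07) and Tnf (-0.09) did not pass. Acta2 passed with trended, robust moderation (adjusted p = 0.0201), and Tnf with the mean of its probe sets (0.186, adjusted p = 0.0116). Limma called 2224 genes, 1260 higher and 964 lower, which became 1399 and 673 with array medians subtracted. The count was 1361 without siNTC PBS replicate 1, 1312 without siNTC Ang II replicate 2, 1384 without siGiver PBS replicate 1 and 1345 without siGiver Ang II replicate 2.

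The 99 genes raised at least 1.5-fold in this average had a median Ang II effect of 0.54 in siNTC cells and 1.155 in siGiver cells. Their median interaction was 0.73 (fry p = 1.12e-05, and p = 0.00117 by camera with an estimated correlation), and 80 of the 99 passed individually with a higher and 5 with a lower effect in siGiver cells. Their median siRNA effect averaged over PBS and Ang II was 0.27 (fry p = 0.000126, and p = 0.0698 by camera with an estimated correlation). With no fold minimum, the siRNA effect over 1260 raised genes was 0.017 and no longer passed, and their interaction was 0.125. Only 3 genes, Ackr3, Tbx18 and Agtr1a, were lowered at least 1.5-fold, with a median interaction of -0.34 (fry p = 0.00164, and p = 0.183 by camera with an estimated correlation). This small set and its median changed with the processing. The median was -0.634 with the mean of a gene's probe sets, -0.264 without siGiver PBS replicate 2 and -0.5204 without siGiver Ang II replicate 1.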

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

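The tests of the interferon and immediate early patterns, and of siRNA sequence or handling of the arms, were chosen after the results were seen. The counts over other splits of the arrays and the test of array scaling were planned.

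A test of the difference between the siRNA arms in the Ang II effect picked out 707 genes. Above 0 were Fam110c (1.93), Serpinb2 (1.76), Akap12 (1.53), Dusp5 (1.52), Nr4a1 (1.503), Rgs16 (1.502), Ptgs2 (1.496), Egr2 (1.48), Sgk1 (1.395), Dusp6 (1.39), Nr4a3 (1.202), Egr1 (0.96) and Fos (0.64). Below 0 were Mx1 (-1.96), Cxcl11 (-1.72), Cxcl9 (-1.61), Zbp1 (-1.497), Ccl5 (-1.31), Ifit3 (-1.28), Ddx60 (-1.24), Ifi27l2b (-1.24), Mpeg1 (-1.23) and Ly6e (-1.12). The Fam110c and Cxcl9 values were taken as bounds, since a siGiver group mean of each lay below the filter value of 4.81 log2. The Ddx60 call was lost with trended, robust moderation (adjusted p = 0.0747) and when any of 5 arrays was left out. The Fos call was lost with the mean of its probe sets (0.17, adjusted p = 0.337). It was also lost without siNTC PBS replicate 2, siNTC Ang II replicate 2 or siGiver Ang II replicate 1. Gene lists whose Ang II effect differed had median interactions of 0.446 for immediate early factors, 0.514 for MAPK and G-protein feedback regulators, 0.065 for inflammatory genes, -0.102 for cell cycle genes, 0.164 for contractile genes, 0.164 for matrix genes, 0.145 for growth factors, -0.738 for interferon response genes and -0.219 for p53 target genes. With an estimated correlation, only the immediate early and interferon lists of these 9 passed.

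Data outside the comparisons held 2 further observations. The 5S ribosomal RNA control probe set was 0.709 log2 higher in siNTC Ang II than in siNTC PBS arrays. Among 5589 probe sets without a single gene symbol, 2097 differed between the siRNA arms. This is a smaller share than the 9512 of all 21729 probe sets tested.

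The siRNA arms differed in 5938 genes, which is 52.2% of those tested. In a plain fit of 4 arrays against 4, the real split gave 4185 genes and the highest of the other splits 28. Thus 1 of 35 splits gave as many, the lowest share that 35 splits can give. The other splits mix the siRNA arms, which widens the spread within each side. Chance is not excluded, because arrays of a group may share a culture, and then fewer divisions are independent. The lower of the counts with cyclic loess or array medians subtracted was 5792, so the count depended little on further scaling of this kind. The deposited values were already quantile normalized, so these tests cannot show a distortion from that step, which stays open. The design holds 1 siRNA per arm, so effects of the siRNA sequences or of separate handling of the arms cannot be told apart from loss of Giver, which stays open as the biological explanation.

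Interferon response genes rose with Ang II in siNTC cells and had a median Ang II effect near 0 in siGiver cells. A single deviating array is argued against, since the lower of the 2 siNTC Ang II arrays had a list median 0.765 above the siNTC PBS mean. A difference between the arms that was present before Ang II is argued against for the list as a set, by its median siRNA effect of 0.0112 in PBS. In PBS, 3 members were higher, 1 was lower and 14 did not pass. It is not argued against for each interferon-inducible gene. In PBS, Gbp4 averaged 8.56 in siGiver and 9.41 in siNTC arrays, and Ccl5 10.12 and 9.73. Only 2 arrays form the group, with no label of separate cultures, so handling of those cultures cannot be told apart from Ang II, and the 5S control stood highest in the same arrays. A changed response to Ang II after Giver siRNA may also underlie the median interaction of -0.738, which was not tested further.

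Immediate early factors rose further with Ang II in siGiver cells. A stretched scale of the siGiver Ang II arrays would move every list raised by Ang II further. The interferon list's median interaction was -0.738, but it cannot decide this. That list's median Ang II effect in siGiver cells was -0.0065, which leaves little to stretch. Nox1, Il6 and Ccl2 rose by 0.44, 0.63 and 0.28 in siNTC cells, and rose in siGiver cells too. Their interactions were 0.0042 (95% interval -0.18 to 0.19), 0.07 (-0.08 to 0.22) and 0.07 (-0.08 to 0.22). For these genes the values argue against a stretch of all raised genes alike, while Nr4a3, Egr1 and Fos did rise further. A lower starting level is argued against for the list as a set, since its median siRNA effect with Ang II was 0.521, above siNTC cells. In PBS, 8 members were lower and 8 higher in siGiver cells. It is not argued against for each gene. In PBS, Nr4a3 averaged 5.76 in siGiver and 6.10 in siNTC arrays, and Serpinb2, outside the list, 5.05 and 6.04. More receptor transcript stays open, because Agtr1a was 0.235 log2 higher in siGiver cells in PBS and no value in these data ties its level to the response.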

How the results depend on the processing

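All alternatives were written before the data were examined. With 2 arrays per group, leaving out any of at least 4 arrays moved each count of Ang II or interaction calls by over 1.5 times, while siRNA counts moved by less. Of the alternative values, 2641 of 2730 for the 195 named gene results kept direction and side of the threshold, 66 lost the call, 4 gained it and 19 changed sign, 2 of which (Tnf with the mean of its probe sets) also gained a call. The cause of the changes was not tested, except that leaving out arrays or fitting 4 arrays leaves fewer to estimate the spread. Part of the 2730 values could not change direction. Trended, robust moderation, the replicate block and leaving out an array outside the groups compared leave the log2 value as it was. Most named genes were also chosen for their large changes in these data, so 2641 of 2730 does not describe other genes. A lone array was assumed to vary like the other groups. Dim probe sets, near 4.81 log2, are limited by their signal over background. The filter value is a percentile and no background level was estimated, so the bounds given for dim genes are an assumption.

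The siNTC Ang II count was 420 without the filter, 1066 with the 50th percentile filter, 1496 with trended, robust moderation, 1302 at adjusted p under 0.1, 96 at unadjusted p under 0.05 and 1.5-fold, 422 with only the 4 arrays compared, and 226 to 526 with 1 array left out. In the same order without the filters, the siGiver Ang II count was 2802, 2878, 230, 1211 and 866 to 1740. The interaction count was 467 without the filter, 1490 with trended, robust moderation, 1275 at adjusted p under 0.1, 212 at unadjusted p and 1.5-fold, and 356 to 435 with 1 array left out. It was 384 and 399 without siNTC PBS replicate 1 or 2, 356 and 374 without siNTC Ang II replicate 1 or 2, 371 and 435 without siGiver PBS replicate 1 or 2, and 432 and 384 without siGiver Ang II replicate 1 or 2. With every probe set tested, siRNA counts were 6042 in PBS, 7751 with Ang II and 9512 averaged, and the averaged Ang II count was 3531. At unadjusted p and 1.5-fold these were 495, 755, 514 and 102. The averaged Ang II count was 1312 to 1699 with 1 array left out.

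With an estimated correlation, lists past the threshold fell from 12 to 3 for Ang II in siNTC cells, from 5 to 0 for the averaged siRNA effect and from 9 to 2 for the interaction. Fry gave 17, 16 and 11. By fry even the reference genes passed for Ang II in siNTC cells (adjusted p = 0.0126) and for the averaged siRNA effect (adjusted p = 0.0102). By camera with an estimated correlation, the siRNA effect on raised genes (0.2675, p = 0.0698) and both effects on the 3 lowered genes (-0.3438, p = 0.183, and -0.3787, p = 0.534) lost their calls. With no fold minimum, the siRNA effect on 1260 raised genes was 0.01677 and lost its call, and their interaction 0.125.

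Signs changed only for Tnf, Egr1 and Nox1 values that had not passed. With the mean of its probe sets, Tnf was 0.2375 in siNTC cells (adjusted p = 0.0395), 0.1341 in siGiver cells and 0.1858 averaged (adjusted p = 0.0116). Its siRNA effect was then -0.2573 with Ang II (adjusted p = 0.00473) and -0.2056 averaged (adjusted p = 0.00203). Its interaction was 0.005602 with cyclic loess and 0.00053 with array medians subtracted. With 1 array left out, Tnf ranged from -0.1829 to 0.01655 for Ang II in siNTC cells, -0.1107 to 0.0292 for the siRNA in PBS, -0.1558 to 0.0437 with Ang II, -0.09826 to 0.001485 averaged, and -0.1151 to 0.08443 for the interaction. Egr1 in PBS ranged from -0.01835 to 0.04285, and the Nox1 interaction from -0.04461 to 0.05303.

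Replicate numbers are shared across groups but only number the arrays. Differences between replicates 1 and 2 correlated at -0.00105 and -0.0655 between the groups of the Ang II comparisons and at 0.0961 and 0.0913 for the siRNA comparisons. With a replicate block, counts were 548, 1603, 3799, 4954, 553, 5813 and 1985 for Ang II in siNTC and siGiver cells, the siRNA in PBS and with Ang II, the interaction, the averaged siRNA and the averaged Ang II effect, all within 1.5 times. Acta2 was then not called for Ang II in siNTC cells (adjusted p = 0.0677) or the siRNA in PBS (adjusted p = 0.0558), and lists stayed at 12, 5 and 9.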

Other observations

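Single genes of redox and sugar metabolism differed between the siRNA arms, averaged over PBS and Ang II, while their lists did not pass. Of 16 antioxidant genes, 7 were higher and 4 lower in siGiver cells (8 and 4 adjusted over the list alone), with the quinone reductase gene Nqo1 at 0.72, Txnrd1 at 0.51, Gclc at 0.49 and Sod2 at -0.42, and the list did not pass (camera adjusted p = 0.123). Of 12 hypoxia and glycolysis genes, 7 were higher and 3 lower (7 and 3 adjusted over the list alone), with Egln3 at -1.44, Pfkfb3 at 0.46 and Hk2 at 1.07 (list adjusted p = 0.442). Hk2 had a higher Ang II effect in siGiver cells by 1.27. The sterol carrier gene Stard4 was higher by 0.85 within a cholesterol list that did not pass (adjusted p = 0.576; median -0.01, mean 0.06). Of 12 p53 target genes, 7 were lower and 1 higher (7 and 1 adjusted over the list alone), with Cdkn1a, a cell cycle inhibitor, at -0.52 (list adjusted p = 0.138).

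Other splits of the 8 arrays were counted with plain fits of 4 against 4. Splits that unbalance the siRNAs or treatments carry those effects, so 3 of these counts decide nothing about chance. For Ang II averaged over both siRNAs, 28 genes passed and 2 of 35 splits gave as many, the highest other being the siRNA split with 4185. For gene lists between the siRNA arms, the real split gave 2, the highest other 9, and 24 of 35 splits gave as many. For the genes raised by Ang II, which were chosen on the treatment, the siRNA split gave a median difference of 0.2675, the treatment split 0.793, and 22 of 35 splits gave as large a value. Tests on the 8 splits with 1 array of each group on either side were chosen after the results were seen. There, this median was at most 0.0189. These are too few for a share under 0.05.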
